A study of Rattus norvegicus with 40 samples.

How the data were processed

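RNA of carotid arteries from male Wistar-Kyoto rats of 3 months, extracted with a column kit and labelled with biotin per the labels, was hybridised to Affymetrix U34A arrays, which hold several short probes per probe set. Per the labels' protocols, 3 vessels were pooled for each of the 40 arrays. The authors deposited one linear intensity per probe set and array. The summary algorithm and software are not given in the sources used here. The deposited intensity values were never below 0, and their mean without the lowest and highest 2% lay near one value on every array, so a scaling of that kind had been applied before deposit. That scaling makes each value relative to the rest of its array. The table held 8799 probe sets, of which 59 were controls and left out, 89 values were 0, and no column was without a sample.

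Values below 23.3, the 20th percentile over all arrays, were raised to it, and log2 was taken, which understates the changes of dim genes. The 2913 probe sets with the lowest mean over all arrays were left out, and 5827 were tested. Gene names came from the platform annotation supplied: 7006 probe sets had 1 symbol, 308 had several and 1426 had no entry and stay unnamed here. The tested probe sets covered 3546 genes, 931 of them by more than 1 probe set, and the probe set with the highest mean over all arrays represents a gene. Probe sets were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on all arrays with 11 group means, which share one estimate of the spread, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene at the floor on all arrays of the lower group has only a bound, given as at least so many fold.

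Before the data were examined, 18 comparisons, 22 gene lists, the settings to be varied and the naming rule were fixed. Some of the lists hold markers of other tissues that the dissected vessel may hold, such as skeletal muscle, nerve and fat. The rule takes, per comparison, the 8 genes with the largest rise and the 8 with the largest fall that pass (4 and 4 for differences of effects; the 3 smallest p each way where none passes), up to 4 members with the smallest p from each list described, and in the left tPA against gel comparisons also a set that includes Plat, Plau, Plaur, Acta2, Myh11, Col1a1, Spp1 and Timp1. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, over 1 probe set per gene. Of 378 list tests 101 passed, and 5 of these held with an estimated correlation. The lists of matrix proteases and inhibitors, mitochondrial energy, and heat shock and oxidative stress passed in no comparison (lowest camera adjusted p = 0.053, 0.0808 and 0.101). Of the neutrophil list only 4 genes were tested, under the 5 needed.

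The fit was tested on simulated data: for left tPA against gel on day 1, with 200 of 5827 probe sets changed, 16% of changes of 2-fold and 78% of changes of 4-fold were called, and 28.5% and 85.5% for left gel against sham on day 4. With no change the fit made 0 calls, and with these changes 2, 13, 3 and 13 false ones. Other splits of the real arrays called up to 220 probe sets, so the simulation does not bound the false calls there. Alternatives were quantile normalization, median scaling, no filter on dim probe sets and one that leaves out 50%, a floor at the 40th percentile, array weights, trend and robust moderation, only the groups compared, the replicate number as a block, the mean of a gene's probe sets, and each array left out. Added after seeing the data were fits without 4 tPA arrays, without 55 probe sets whose upper quartile exceeded 2000 and whose lowest value lay below 100, with left gel day 1 replicates 1 and 3 averaged, and list tests without right gel day 1 replicate 3. That pair's SD of log2 differences, 0.45, was the lowest of 60 pairs within groups (median 0.838), with values not identical. Sham day 1 replicates 1 and 2 (0.489) and 3 and 4 (0.532) came next, with 0.732 to 0.787 across these pairs. Whether these arrays were independent was not tested. Same-numbered arrays all deviated together (correlation above 0.1) in 1 of the 14 comparisons of 2 groups, right gel against sham on day 1, where the labels give no shared animals. No hybridisation batch was given in the sources used here.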

Results

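Gene expression was measured in rat carotid arteries after balloon injury, in which an inflated catheter strips the inner lining of the vessel and stretches its wall. The outer side of the injured left common carotid artery then received plain pluronic gel, a carrier, or gel with tPA (tissue plasminogen activator, a protease that turns plasminogen into plasmin), given as recombinant protein at 20 nmol/kg. Left and right arteries were taken on day 1 or day 4. Each of these 8 groups had 3 arrays. Left arteries of sham-operated rats gave 4 arrays on day 1 and 6 on day 4, and those of intact rats gave 6, making 40 arrays in 11 groups. RNA of 3 vessels was pooled for each array. The arrays had nearly one trimmed mean, from 500.3 to 500.8 intensity units, with medians from 103.2 to 168.3. The number of arrays limits the precision of every value. Differences are on the log2 scale, first group minus second, and a value in parentheses after a gene name is such a difference. Adjusted p-values are those of limma for genes and of camera for lists.

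An injury index was formed from the 639 probe sets higher and 531 lower in left gel than in sham arteries, using gel, sham and intact arrays alone. It lay between 1.06 and 1.27 in left gel arrays on day 1 and between 1.92 and 1.95 on day 4, by construction above right gel, sham and intact arrays (-1.28 to 0.16). Among the tPA arrays 4 stood apart from their group. The arrays labelled right tPA day 4 replicate 1 and right tPA day 1 replicate 2 had indices of 1.25 and 1.30. Those labelled left tPA day 4 replicate 1 and left tPA day 1 replicate 2 had -0.66 and -0.18. Outside these 4, right gel day 1 replicate 3 had 6.57% of its values at the floor, against 15.6 to 25.2% in the other arrays, the highest median (168.3) and a correlation across probe sets of -0.11 with the rest of its group. Labels were kept as deposited in every comparison. Counts without these 4 arrays stand beside each comparison, a choice made after seeing the data that rests on the outcome itself. In comparisons that hold no tPA group these arrays enter through the shared estimate of the spread alone.

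Array quality differed between some groups, a comparison chosen after seeing the data. Over 5 measures and 14 comparisons of 2 groups, 8 of 70 tests showed groups whose values did not overlap, where chance gives 4.27. A 3'/5' ratio compares control probes at both ends of a transcript, and a higher one means less signal at the 5' end relative to the 3' end. The actin ratio lay at 7.38 to 8.09 in left gel arrays of day 4, below left tPA (11.02 to 16.02), right gel (11.68 to 13.61) and sham arrays (11.83 to 23.69) of that day. In right gel arrays of day 1 it lay at 10.25 to 15.25, below sham (16.26 to 21.11), and the GAPDH ratio at 3.25 to 5.61, below sham (7.53 to 10.26) and left gel (6.47 to 9.04). The share of values at the floor was 17.4 to 20.3% in left tPA and 21.2 to 24.8% in left gel arrays of day 1. In right gel arrays of day 4, 8 to 10 bright probe sets read near 0, against 0 to 5 in sham.

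**Figure D1:**
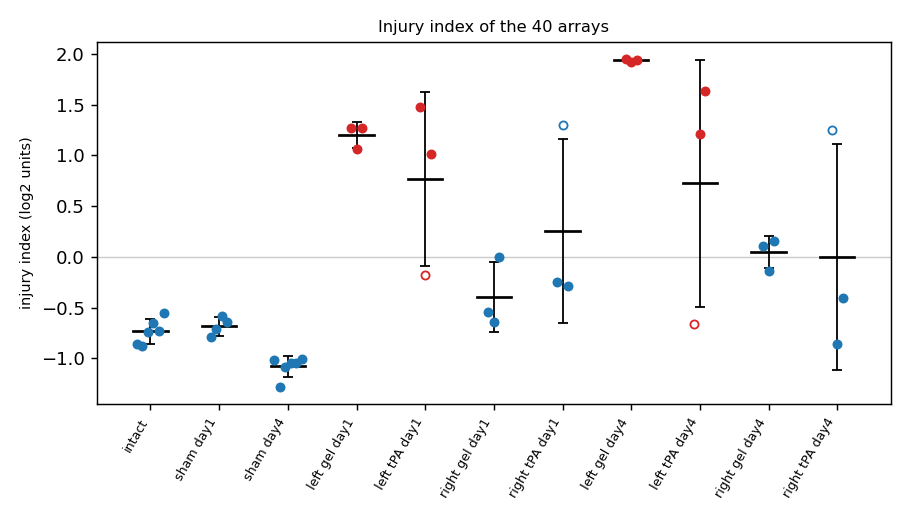
Injury index (vertical axis, log2 units) of each of the 40 arrays by group (horizontal axis); red points are left arteries of ballooned rats, blue points all other arrays, open points the 4 tPA arrays that stood apart, and bars the group mean with its SD. Open points of right arteries lie at 1.25 and 1.30, and those of left arteries at -0.66 and -0.18.

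The first question was what tPA changed in the injured artery against the carrier. On day 1, genes of cell division were lower with tPA. Cdk1, the kinase that starts mitosis, was at 6.65 ± 0.48 (SD, n = 3) against 9.77 ± 0.47 (SD, n = 3) (log2 intensity, tPA against gel), a fall of 8.7-fold (95% interval 3.34 to 22.7) with an adjusted p = 0.0498. Cenpw, a centromere protein, Smc4, a chromosome condensation protein, and Pcna, the sliding clamp of DNA replication, fell too (-2.71, -2.29 and -1.38, SE 0.55, 0.46 and 0.29). Of 24 cell cycle genes tested, 2 fell and 22 did not pass, with 0 higher and 17 lower adjusted over the list alone (camera adjusted p = 5.54e-18, and adjusted p = 0.0251 with an estimated correlation). Their mean difference was -1.41. Top2a (-3.03) and Ccne1 (-1.27), both with adjusted p = 0.062, did not pass, and another probe set of each had a difference above 0. On the scale centred over all arrays, the list mean was 1.01 to 1.31 in left gel and -0.35 to -0.10 in left tPA arrays, and 1.38 in the array labelled right tPA day 1 replicate 2. Adora2a, an adenosine receptor, rose (1.64, SE 0.30, adjusted p = 0.0232). In 2 of the 3 tPA arrays both control 3'/5' ratios lay below those of every gel array (GAPDH 2.18 and 0.243 against at least 6.47, actin 9.10 and 2.80 against at least 13.36). In all 7 probe sets passed (1 higher, 6 lower). Quantile normalization gave 11, median scaling 41, a floor at the 40th percentile 41, a filter that leaves out 50% of probe sets 29, array weights 128 and the replicate number as a block 0. The last 2 of the 7 probe sets were one of Tpm1, a tropomyosin (-4.42), named after its value was seen because it is not the gene's brightest, and 1 without a gene name. When the 4 tPA arrays that stood apart were left out, 115 (23 higher and 92 lower) passed. The count moved by over 1.5 times with replicates 1, 2 and 3 left out in turn. It was 0, 20 and 0 for left gel and 132, 24 and 0 for left tPA. With left gel replicates 1 and 3, the most alike arrays within any group, averaged, 0 passed, and with only these 2 groups fitted 0 did.

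Lists of other cell types differed between the same arrays. None of 23 skeletal muscle markers passed, and 5 were lower adjusted over the list alone (camera adjusted p = 4.87e-05, and adjusted p = 0.369 with an estimated correlation). Their mean was 1.90 ± 0.43 (SD, n = 3) in left gel and 0.22 ± 1.70 (SD, n = 3) in left tPA arteries. Tnnc2, fast muscle troponin C, had a difference of -5.19 (adjusted p = 0.062). Nerve, adipocyte, endothelial, immediate early and antigen presentation lists lay higher with no member past (camera adjusted p = 0.00707, 0.00439, 0.0366, 0.0366 and 0.0366). Contractile smooth muscle and matrix lists lay lower, again with no member past (camera adjusted p = 0.0366 and 0.0216). For each of these 7 lists, adjusted p = 0.369 with an estimated correlation. The nerve, adipocyte and endothelial calls ended without the 4 arrays that stood apart (camera adjusted p = 0.619, 0.0734 and 0.254). No tested gene of the fibrinolytic and structural set chosen in advance passed: Plat (-0.60), Plau (0.81), Plaur (0.10), Spp1 (-0.76), Acta2 (-0.15), Myh11 (-0.87), Col1a1 (0.09) and Timp1 (0.19) had adjusted p from 0.39 to 0.959. Plat encodes tPA itself, and Plau and Plaur encode urokinase and its receptor. Other probe sets of Acta2, Myh11 and Timp1 had the opposite sign, and Plaur and Col1a1 changed sign with median scaling.

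On day 4, 7 probe sets separated tPA from gel in the left artery (4 higher, 3 lower). Adra1d, an adrenergic receptor of smooth muscle, rose 6.14-fold (95% interval 3.13 to 12), from 5.19 ± 0.82 to 7.80 ± 0.94 (SD, n = 3 each, limma adjusted p = 0.0192). Eln, which encodes elastin, fell (-5.61, SE 1.22, adjusted p = 0.0488), through a probe set that read near 0 on some arrays. Dbp (3.56), Tgfb3 (1.91), Igf1 (-1.60) and RT1-Bb (-2.12) passed through probe sets that are not their brightest, and were named after their values were seen. The macrophage list lay lower with no member past (camera adjusted p = 0.0021, and adjusted p = 0.382 with an estimated correlation), Lgals3 and Fcgr2b having differences of -1.12 and -1.78. The contractile list lay higher with none past (camera adjusted p = 0.00788, and adjusted p = 0.382 with an estimated correlation), Gucy1b1 having 1.04. Endothelial, lymphocyte, matrix, nerve and ribosomal protein lists lay lower (camera adjusted p = 0.0115, 0.034, 0.0411, 0.0309 and 0.0118). For these, adjusted p = 0.382, 0.513, 0.382, 0.576 and 0.513 with an estimated correlation. In the set chosen in advance none passed: Plat (-0.25), Plau (-0.58), Plaur (-0.57), Spp1 (-0.89), Acta2 (-0.19), Myh11 (1.03), Col1a1 (-0.17) and Timp1 (-0.42) had adjusted p of at least 0.529. With the 4 tPA arrays that stood apart left out, 21 (9 higher and 12 lower) probe sets passed, the contractile and lymphocyte calls ended (camera adjusted p = 0.401 and 0.497), and Plat and Plau took the opposite sign. With 1 array fewer the count moved by over 1.5 times, as omitting left gel replicates 1, 2 and 3 gave 2, 0 and 3 in turn and omitting left tPA replicates 2 and 3 gave 4 and 17 in turn. With only these groups fitted, or the replicate number as a block, 0 passed, and no filter gave 12, a floor at the 40th percentile 16 and array weights 339.

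Injury under plain gel was compared with the sham operation of the same day. On day 1, 182 probe sets passed (97 higher, 85 lower), or 150 named genes. Cxcl2, a chemokine that draws neutrophils, rose from 4.73 ± 0.38 (SD, n = 4) to 10.24 ± 2.86 (SD, n = 3), with a limma adjusted p = 0.00493. Cell cycle genes rose, 10 of 24, with 20 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.93e-18, and adjusted p = 0.0233 with an estimated correlation), among them Ccne1 (1.81), Rfc4 (2.23), Hmgb2 (2.41) and Pcna (1.31). Skeletal muscle markers rose, 8 of 23, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.87e-12, and adjusted p = 0.141 with an estimated correlation), among them the sarcomere genes Myh4 (6.47), Myl3 (5.92), Tnnc2 (5.74) and Myh7 (5.52). Their mean, centred over all arrays, was 1.585 to 2.387 in left gel arrays. Single arrays of uninjured arteries came as high: intact replicate 3 had 1.63 and right gel day 4 replicate 1 had 1.79. Right tPA day 1 replicate 3 had 1.86. The other intact, right gel day 4 and right tPA day 1 arrays had 0.77 or less. Muscle tissue held by the dissected vessel was not told apart from a response to injury. In the growth factor list 4 fell, with 0 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.00834, and adjusted p = 0.202 with an estimated correlation). Ccl11, an eosinophil chemokine, fell at least 38.1-fold, and Cyp2c11 at least 42.1-fold. Igfbp5, an insulin-like growth factor binding protein, fell (-3.42), as did Rnase1 (-3.93), Gpc3 (-3.05) and Bmp4 (-2.98). Ccl11, Cyp2c11 and Igfbp5 were also lower than sham in uninjured right gel arteries of day 1. Cyp2c11 and Igfbp5 were higher in sham of day 1 than in intact arteries, so these falls are not particular to the injured artery. Of the 4 neutrophil genes tested, S100a8 (3.93) and Defa5 (3.06) passed, and S100a9 (3.51) and Cxcr2 (-0.21) did not, too few genes for the list test. Col1a2 rose (6.83) through a probe set that read near 0 on some arrays. Without the 4 tPA arrays that stood apart, 430 passed. Omitting each array in turn moved the count by over 1.5 times. It was 110, 112, 109 and 115 for sham and 90, 98 and 92 for left gel.

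By day 4 the injured artery under gel differed from sham in 1117 probe sets (657 higher, 460 lower), or 828 named genes, with actin 3'/5' ratios that did not overlap either. Complement C3 rose to 9.30 ± 0.62 (SD, n = 3) from 4.76 ± 0.39 (SD, n = 6) in sham, 23.2-fold (95% interval 7.25 to 74.4). Rises were also seen for Il1b (4.62), Il18 (4.46), Ccl2 (3.73) and Cxcl13 (4.79). In the cytokine list 7 rose and 1 fell, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0408, and adjusted p = 0.355 with an estimated correlation). Of 12 macrophage markers 9 rose, with 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.92e-06, and adjusted p = 0.0872 with an estimated correlation), among them Lgals3 (2.74), Ctss (1.89) and Aif1 (3.83). Of 12 lymphocyte markers 6 rose, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000509, and adjusted p = 0.118 with an estimated correlation), among them Cd37 (2.83), Cd53 (4.12) and Cd8a (3.91). In the antigen presentation list 9 rose and 1 fell, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00544, and adjusted p = 0.259 with an estimated correlation), the class II genes RT1-Ba (2.98) and RT1-Db1 (3.97) among them. Cell cycle genes rose, 19 of 24, while 2 fell, with 20 higher and 2 lower adjusted over the list alone (camera adjusted p = 2.72e-09, and adjusted p = 0.111 with an estimated correlation). Examples were H2az1 (2.61), Top2a (4.20), Cdk1 (3.63) and Ccnb1 (3.25).

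In the same day 4 arrays other lists fell. Contractile smooth muscle genes fell, 9 of 20, with 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 5.34e-08, and adjusted p = 0.0341 with an estimated correlation), among them Myh11 (-2.20), Itga7 (-1.87), Gucy1b1 (-1.52) and Cnn1 (-1.59). Another probe set of Myh11, smooth muscle myosin, had the opposite sign. In the ion channel and calcium handling list 3 fell and 1 rose, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0276, and adjusted p = 0.118 with an estimated correlation), among them Cacnb2 (-1.59) and Itpr1 (-2.24). Tnn (tenascin N), Thbs4 (a thrombospondin) and Esm1 (an endothelial proteoglycan) rose by 5.13, 4.99 and 4.52 on the log2 scale. Bmp4 fell at least 20.8-fold, and Omd (-4.34), Adra1d (-3.77) and Slc2a4 (-3.56) fell. The sodium channel gene Scn7a rose (5.48), its second probe set having -0.30. Of 37 ribosomal protein genes 3 fell, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00124, and adjusted p = 0.333 with an estimated correlation). Apoe fell at least 174-fold, and Tuba1b (-7.30), Snrnp70 (-4.09) and Obp3 (-4.91) fell, through probe sets that read near 0 on some arrays. Second probe sets of Apoe and Snrnp70 had 2.99 and 2.49. Scaling every array to one median would lower all differences of this comparison by 0.13, giving 542 higher and 592 lower. The same shift was 0.14 for left tPA against gel on day 1, 0.16 and 0.14 for left tPA against sham on days 1 and 4, 0.12 and 0.10 for right gel against sham, -0.13 for the tPA effect by day and 0.11 for the injury effect by day. When the 4 tPA arrays that stood apart were left out, 1310 passed. When 1 array was left out the count moved by over 1.5 times, as omitting left gel replicate 1 gave 723.

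Under tPA the injury response of day 1, against sham, held 258 probe sets (94 higher, 164 lower). Hp, haptoglobin, rose 6.87-fold (95% interval 3.2 to 14.8), from 7.23 ± 0.42 (SD, n = 4) to 10.01 ± 0.95 (SD, n = 3). The chemokine gene Cxcl2 (3.76), the interleukin gene Il1b (3.63), the prostaglandin receptor gene Ptgfr (2.77) and Enpp3 (3.63) rose, and so did Hmox1 (3.04), heme oxygenase 1, through a probe set that read near 0 on some arrays. In the cytokine list 4 rose and 2 fell, with 11 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0258, and adjusted p = 0.531 with an estimated correlation). Of the macrophage markers 1 rose, Cd14 (1.72), with 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0345, and adjusted p = 0.606 with an estimated correlation). Contractile genes fell, 4 of 20, with 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00119, and adjusted p = 0.493 with an estimated correlation), among them Gucy1a1 (-1.64) and Myh11 (-1.59), another probe set of Myh11 having the opposite sign. Cyp2c11 fell at least 42.1-fold, with falls of Ccl11 (-3.43), Omd (-3.11) and Bmp4 (-2.97). Cyp2c11 and Ccl11 were also lower than sham in uninjured right gel arteries of day 1. The cell cycle list did not pass (camera adjusted p = 0.864). With the 4 tPA arrays that stood apart left out, 682 (309 higher and 373 lower) passed, with only the groups compared, 54, and with the replicate number as a block, 1. Median scaling gave 59 higher and 239 lower. The count moved by over 1.5 times with replicates 1, 2 and 3 left out in turn. It was 150, 91 and 128 for sham and 98, 485 and 27 for left tPA.

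On day 4 the tPA-treated injured artery differed from sham in 342 probe sets (230 higher, 112 lower). Cell cycle genes rose, 14 of 24, with 21 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.09e-11, and adjusted p = 0.0516 with an estimated correlation), among them H2az1 (1.92), Cdk1 (3.09) and Top2a (2.96). Of 12 macrophage markers 5 rose, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000651, and adjusted p = 0.141 with an estimated correlation), among them Lgals3 (1.62), Aif1 (2.62) and Ctss (1.20). Of the lymphocyte markers 3 rose, with 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00552, and adjusted p = 0.174 with an estimated correlation). The macrophage elastase gene Mmp12 rose 8.82-fold (95% interval 3.35 to 23.3) to 9.38 ± 2.04 (SD, n = 3), and Esm1 rose too (3.59). Contractile genes lay lower, 2 falling, Cnn1 (-1.27) and Acta2 (-0.68), with 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 2.03e-06, and adjusted p = 0.051 with an estimated correlation). Of 37 ribosomal protein genes 7 fell, with 0 higher and 15 lower adjusted over the list alone (camera adjusted p = 2.33e-11, and adjusted p = 0.051 with an estimated correlation). Ion channel, matrix and glycolysis lists lay lower and antigen presentation higher (camera adjusted p = 0.0211, 0.0301, 0.04 and 0.0192). For these 4, adjusted p = 0.0982, 0.174, 0.0761 and 0.268 with an estimated correlation, and the matrix and glycolysis calls ended without the arrays that stood apart (camera adjusted p = 0.0645 each). Eln, Tuba1b and Grn fell (-6.75, -5.23 and -4.54) through probe sets that read near 0 on some arrays, and a second probe set of Grn had 0.63. Without the 4 tPA arrays that stood apart, 1053 (670 higher and 383 lower) probe sets passed, with only the groups compared, 16, with the replicate number as a block, 0, and with array weights, 1400. Median scaling gave 152 higher and 166 lower. With 1 array fewer the count moved by over 1.5 times, as omitting left tPA replicates 1, 2 and 3 gave 877, 22 and 6 in turn.

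The injury responses with gel and with tPA shared 22 probe sets higher and 33 lower on day 1, and 208 and 58 on day 4. In opposite directions 0 were called. Independent lists would share 1.56, 2.39, 25.9 and 8.84. With the sham arrays divided between both comparisons, which lowers their counts too, the overlaps were 0, 1, 19 and 1. The covariance of the fold changes was 0.388 on day 1 and 0.601 on day 4 across probe sets, which are not independent replicates. The sampling spread of the shared sham arrays alone would give 0.0958 and 0.0639. A shift common to the sham arrays of a day adds to overlap and covariance, also with these arrays divided. Sham differed from intact arteries in 55 probe sets on day 1 and 22 on day 4. Overlap and covariance therefore cannot tell a shared injury response from such a shift. Without the 4 arrays that stood apart the overlaps were 105, 124, 492 and 218.

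Injured left and uninjured right arteries of gel-treated rats were compared on each day. On day 1, 32 probe sets passed (12 higher, 20 lower on the left). Mcm5 and Rfc4, genes of DNA replication, rose (2.41 and 1.93, SE 0.58 and 0.40, n = 3 each, limma adjusted p = 0.044 and 0.0394). Of the cell cycle genes 2 rose, with 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.37e-13, and adjusted p = 0.104 with an estimated correlation). Serpine2, a protease inhibitor, and F3, tissue factor, fell (-2.93 and -2.64). Of 23 skeletal muscle markers 1 rose, Tnnc2 (5.64), with 9 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.15e-09, and adjusted p = 0.294 with an estimated correlation). Macrophage markers lay higher with none past and 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0038, and adjusted p = 0.366 with an estimated correlation). Of the adipocyte markers 1 fell, Scd (-2.77), with 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0061, and adjusted p = 0.427 with an estimated correlation). When the 4 tPA arrays that stood apart were left out, 277 probe sets passed. Median scaling gave 46 higher and 19 lower. Omitting replicates 1, 2 and 3 in turn moved the count by over 1.5 times. It was 0, 61 and 50 for right gel and 3, 59 and 3 for left gel.

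On day 4, 297 probe sets differed between left and right arteries under gel (95 higher, 202 lower on the left). Tnn rose 13.3-fold (95% interval 5.15 to 34.5), to 11.66 ± 0.20 (SD, n = 3), and Arg1 (3.65), Mmp12 (3.18) and Il1b (3.07) rose. In the matrix list 3 rose, Col12a1 (2.86), Postn (1.59) and Spp1 (2.08), and 2 fell, Fmod (-2.06) among them, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00187, and adjusted p = 0.154 with an estimated correlation). Of the cell cycle genes 6 rose, with 16 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.03e-08, and adjusted p = 0.154 with an estimated correlation), among them Mcm5 (2.39), Cdc20 (2.06) and Top2a (2.77). Cytokine, macrophage, lymphocyte and antigen presentation lists lay higher, with 3, 1, 2 and 2 members rising (camera adjusted p = 0.00774, 0.00475, 0.00774 and 0.0222). For these, adjusted p = 0.195, 0.195, 0.195 and 0.266 with an estimated correlation. In the plasminogen activation list Tfpi (2.06), an inhibitor of tissue factor, rose and F3 (-2.11), tissue factor, fell, while Plau and Plat, with 1.46 and 1.31, did not pass (camera adjusted p = 0.0452, and adjusted p = 0.195 with an estimated correlation). That call ended without the arrays that stood apart (camera adjusted p = 0.0591). The contractile list lay lower (camera adjusted p = 0.0264, and adjusted p = 0.266 with an estimated correlation). Of 19 nerve and Schwann cell markers 6 were lower on the left, with 1 higher and 11 lower adjusted over the list alone (camera adjusted p = 1.68e-07, and adjusted p = 0.154 with an estimated correlation), their mean being 0.32 ± 0.61 (SD, n = 3) in left and 2.02 ± 0.36 (SD, n = 3) in right arteries. Sham arrays of day 4 had -0.81 to -0.20, so the left mean did not lie below sham and the right arteries were the ones far from it. Of the adipocyte markers 4 were lower on the left, with 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.000551, and adjusted p = 0.195 with an estimated correlation), and skeletal muscle markers lay lower with none past (camera adjusted p = 0.0222, and adjusted p = 0.463 with an estimated correlation). In the adipocyte list, too, right gel arteries of day 4 lay above sham. With the 4 tPA arrays that stood apart left out, 516 probe sets passed. With replicates 1, 2 and 3 left out in turn the count moved by over 1.5 times. It was 190, 155 and 79 for right gel and 118, 174 and 138 for left gel.

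**Figure D2:**
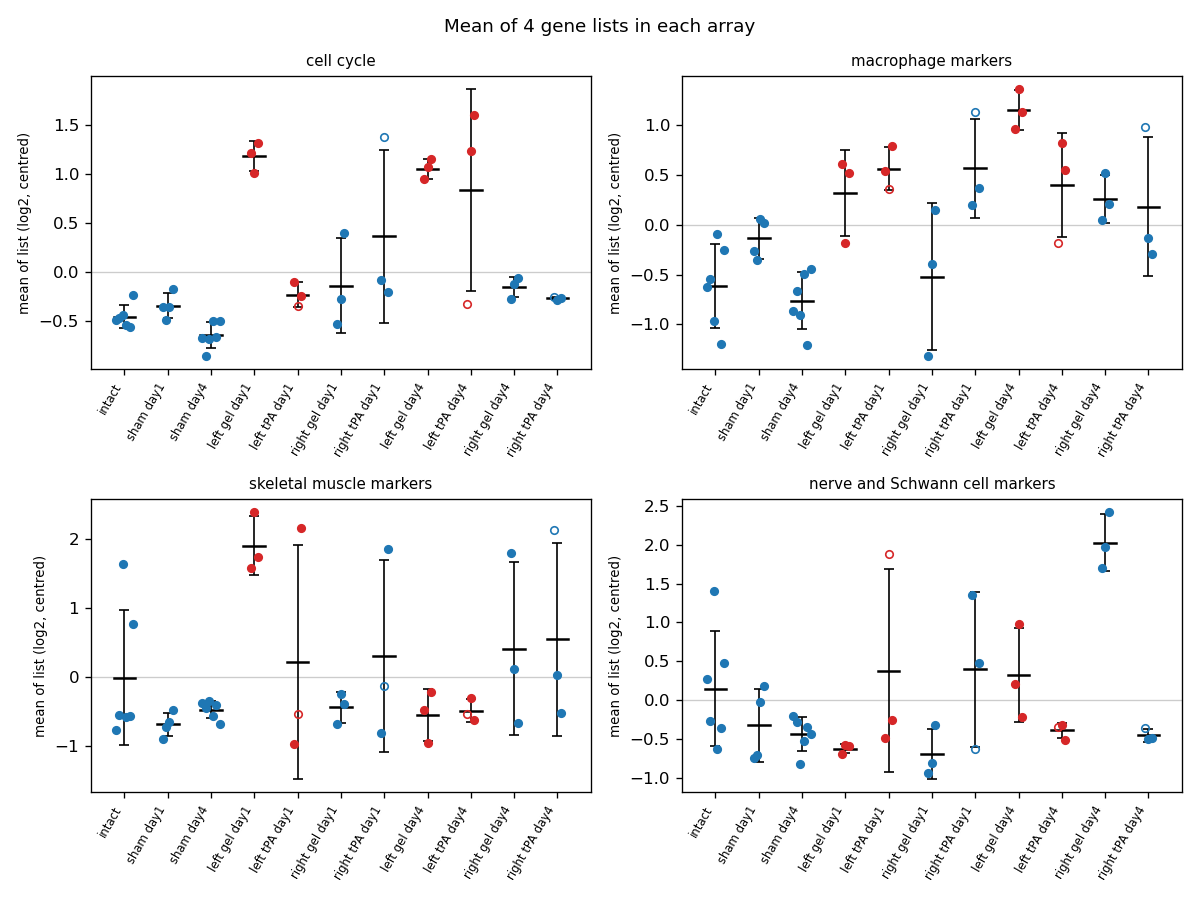
Mean of 4 gene lists in each array (vertical axis, log2 units, each probe set centred over the 40 arrays) by group (horizontal axis), with group mean and SD; red points are left arteries of ballooned rats, blue points all others, and open points the 4 tPA arrays that stood apart. Left gel arrays of day 1 averaged 1.18 in the cell cycle list and left tPA arrays -0.23, and right gel arrays of day 4 averaged 2.02 in the nerve list.

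The right artery was compared to see whether tPA on the left side went with a difference on the other. On day 1 limma called 0 of 5827 probe sets, and 558 had an unadjusted p under 0.05 where chance gives 291.4. The smallest p-values belonged to Lama3, Cd247 and Cyth2 on the higher side (1.51, 1.71 and 0.93) and to Cox4i2, Plb1 and Slc28a1 on the lower (-1.11, -1.78 and -0.80), with n = 3 each and limma adjusted p of at least 0.114. Macrophage, lymphocyte, nerve, cell cycle and antigen presentation lists lay higher, and contractile and ribosomal protein lists lower (camera adjusted p = 0.000299, 0.00396, 0.000723, 0.0116, 0.00545, 0.00195 and 0.00604). For these, adjusted p = 0.365, 0.365, 0.416, 0.563, 0.365, 0.365 and 0.553 with an estimated correlation. Without the 4 arrays that stood apart the cell cycle, antigen presentation and contractile calls ended (camera adjusted p = 0.634, 0.14 and 0.052), and 13 probe sets passed. Without right gel replicate 3 the antigen presentation call ended (camera adjusted p = 0.0898). The count moved by over 1.5 times with single arrays left out, as omitting right gel replicate 3 gave 4 and omitting right tPA replicate 1 gave 3.

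On day 4, 95 probe sets passed between right arteries of tPA and gel animals (6 higher, 89 lower). Nefm and Nefl, neurofilament subunits, Prph (peripherin), Chrna3 (a ganglionic acetylcholine receptor) and Gap43 fell by 6.03, 5.27, 5.49, 5.38 and 3.79 on the log2 scale. Dbh, which makes noradrenaline, fell at least 81.4-fold. Of 19 nerve and Schwann cell markers 8 fell and 11 did not pass, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 5.42e-16, and adjusted p = 0.0223 with an estimated correlation). Their mean was -0.45 ± 0.08 (SD, n = 3) with tPA and 2.02 ± 0.36 (SD, n = 3) with gel, against -0.43 ± 0.22 (SD, n = 6) in sham. Of the arrays that stood apart, right tPA day 4 replicate 1 had -0.35 and left tPA day 1 replicate 2 had 1.88. The mean difference of the list was -2.47, and -2.52 without the 4. Of the adipocyte markers 1 fell, Scd (-3.17), with 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.000329, and adjusted p = 0.404 with an estimated correlation). Ptgs2, cyclooxygenase 2, and Rab4b rose (2.68 and 1.90). Apoe rose (6.73) through a probe set that read near 0 on some arrays, and another gave -1.24. Without the 4 tPA arrays that stood apart, 114 (10 higher and 104 lower) passed. Omitting right gel replicate 3 gave 34 and omitting right tPA replicate 2 gave 60, moves of over 1.5 times.

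The right artery under gel was also set against sham, whose arteries were left carotids, so that side and operation change together. On day 1, 54 probe sets passed (31 higher, 23 lower). RT1-Db1, a class II gene, fell to 7.22 ± 0.51 (SD, n = 3) from 11.15 ± 0.09 (SD, n = 4). Also lower were Ccl11 (-5.09), Cyp2c11 (-4.62) and Igfbp5 (-2.48) and the clock gene Bmal1 (-2.06), and Rpl30 (2.15), Rpl17 (2.09) and Map4k4 (1.96) rose. Adipocyte markers lay higher with none past and 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0472, and adjusted p = 0.941 with an estimated correlation). Without right gel replicate 3, which had few values at the floor, 38 probe sets passed (11 higher, 27 lower) and the adipocyte call ended (camera adjusted p = 0.174). Arrays with the same replicate number deviated together in this comparison (correlation 0.117 to 0.284 across probe sets), and with that number as a block 12 probe sets passed. When the 4 tPA arrays that stood apart were left out, 75 passed. Median scaling gave 24 higher and 31 lower. Single arrays moved the count by over 1.5 times, as omitting sham replicates 3 and 4 gave 16 and 29 in turn and omitting right gel replicate 1 gave 24.

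On day 4 right gel arteries differed from sham in 514 probe sets (363 higher, 151 lower). Of 19 nerve and Schwann cell markers 10 rose and 2 fell, with 13 higher and 2 lower adjusted over the list alone (camera adjusted p = 5.01e-08, and adjusted p = 0.112 with an estimated correlation), among them Nefm (6.07), Dbh (6.06) and Uchl1 (3.90). Sncg, synuclein gamma, rose 89.2-fold (95% interval 19.2 to 416), to 11.48 ± 0.06 (SD, n = 3). Of 18 adipocyte markers 6 rose, with 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000188, and adjusted p = 0.177 with an estimated correlation), among them Cfd (2.25), Scd (3.08) and Lpl (3.17). Of the macrophage markers 2 rose, Lgals3 (1.86) and Ctss (1.41), with 2 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00384, and adjusted p = 0.274 with an estimated correlation). Contractile genes lay lower, 3 falling, Cnn1 (-1.21) and Pln (-2.02) among them, with 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 1.31e-05, and adjusted p = 0.0871 with an estimated correlation). Of the matrix genes 3 fell, with 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.000127, and adjusted p = 0.0712 with an estimated correlation), among them Col1a1 (-0.70), another probe set of which had the opposite sign. Of the ribosomal protein genes 6 fell, with 0 higher and 12 lower adjusted over the list alone (camera adjusted p = 3.51e-07, and adjusted p = 0.121 with an estimated correlation). Apoe, Tuba1b and Eln fell (-7.17, -6.99 and -3.52) through probe sets that read near 0 on some arrays, and a second probe set of Apoe had 2.52. Median scaling gave 308 higher and 219 lower. With the 4 tPA arrays that stood apart left out, 730 passed. When 1 array was left out the count moved by over 1.5 times, as omitting right gel replicate 3 gave 175.

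Sham arteries were set against intact ones to see what the operation alone went with. On day 1, 55 probe sets passed (23 higher, 32 lower). Bmal1, an activator in the circadian clock, rose 14.5-fold (95% interval 8.27 to 25.4), to 9.68 ± 0.35 (SD, n = 4) from 5.82 ± 0.72 (SD, n = 6). Nr1d1 and Nr1d2, repressors in the clock, and its output gene Dbp fell (-1.42, -2.82 and -3.56). Clock genes were no list fixed in advance, and the time of day of tissue collection was not given in the sources used here. Cyp2c11, a cytochrome P450, Igfbp5 and the phosphodiesterase gene Pde7a rose (4.19, 2.81 and 2.67). Of 12 lymphocyte markers 2 rose, Cd3g (2.27) and Cd247 (1.22), with 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00196, and adjusted p = 0.287 with an estimated correlation). Median scaling gave 30 higher and 25 lower. Without the 4 tPA arrays that stood apart, 89 passed. The count moved by over 1.5 times with single arrays left out, as omitting sham replicate 3 gave 36.

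On day 4 sham differed from intact in 22 probe sets (9 higher, 13 lower). Sqle, squalene epoxidase of sterol synthesis, fell and was at 8.47 ± 0.19 against 9.70 ± 0.55 (SD, n = 6 each, limma adjusted p = 0.0184), and Insig1 (-1.34), Scd2 (-1.23) and Msmo1 (-0.85) fell with it. These genes were no list fixed in advance, and another probe set of Scd2 had the opposite sign. Tubb2b, a tubulin, fell too (-1.72). Ribosomal protein, contractile, red cell and immediate early lists lay higher and nerve markers lower, with no member past (camera adjusted p = 6.58e-05, 0.024, 0.0325, 0.0325 and 0.0396). For these, adjusted p = 0.405, 0.423, 0.405, 0.405 and 0.644 with an estimated correlation. When the 4 tPA arrays that stood apart were left out, 30 probe sets passed. With 1 array fewer the count moved by over 1.5 times, as omitting sham replicates 2, 5 and 6 gave 14, 12 and 0 in turn and omitting intact replicates 1, 2, 3, 4, 5 and 6 gave 0, 13, 5, 0, 10 and 13 in turn.

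Differences between effects were tested directly. By side, the cell cycle list responded to tPA on day 1 with lower values in the left artery relative to the right (camera adjusted p = 1.16e-16, and adjusted p = 0.0361 with an estimated correlation), with a mean difference of -1.91 and 0 higher and 14 lower adjusted over the list alone. Without the arrays that stood apart the tPA effect on this list was -1.355 on the left and 4.27e-05 on the right. With all arrays it was 0.50 on the right. There the array labelled replicate 2 had a list mean of 1.38, and replicates 1 and 3 had -0.08 and -0.21. Skeletal muscle markers were lower and adipocyte markers higher in the same test (camera adjusted p = 0.000102 and 0.00176, and adjusted p = 0.552 for both with an estimated correlation), and the adipocyte call ended without the arrays that stood apart (camera adjusted p = 0.0768). Over single probe sets limma called 0, and 662 had an unadjusted p under 0.05. On day 4, 3 passed, those of Resp18 (3.83) and Rab4b (-3.84) and of Gnas (-6.03), the last named after its value was seen. The Gnas probe set read near 0 on some arrays, and in right tPA against gel on day 4 it had 5.74 where the mean of the gene's 3 other probe sets was -1.83. Nerve and adipocyte lists were higher, and matrix, cytokine, macrophage and ribosomal protein lists lower (camera adjusted p = 3.74e-07, 0.025, 0.0176, 0.00257, 0.0176 and 0.0409). For these, adjusted p = 0.243, 0.551, 0.243, 0.243, 0.538 and 0.551 with an estimated correlation. The adipocyte, cytokine and macrophage calls ended without the arrays that stood apart (camera adjusted p = 0.0822, 0.0934 and 0.739). Without these 4 arrays 16 and 5 probe sets passed on days 1 and 4. With single arrays left out both counts moved by over 1.5 times. Omitting right tPA replicate 1 and left tPA replicate 2 of day 1 gave 9 and 7 in turn. On day 4, omitting replicate 2 of right gel and left gel gave 7 and 6. Omitting replicate 3 of right tPA and left tPA gave 12 and 5.

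The response to tPA in the left artery differed between days in 5 probe sets (2 higher, 3 lower on day 4). Mmp16, a membrane metalloproteinase, was higher on day 4, and Apod, Selp (P-selectin) and Rab4b lower (2.35, -5.89, -2.86 and -3.35, SE 0.48, 1.22, 0.59 and 0.64), beside a probe set of Bdnf (4.21), named after its value was seen. Contractile, cell cycle and skeletal muscle lists were higher on day 4, and cytokine, macrophage, lymphocyte, endothelial, adipocyte, nerve and antigen presentation lists lower (camera adjusted p = 0.000983, 3.69e-07, 0.00428, 0.0241, 0.0111, 0.0262, 0.00189, 0.0106, 0.000983 and 0.0106). With an estimated correlation, adjusted p = 0.228, 0.228, 0.355, 0.302, 0.302, 0.302, 0.228, 0.302, 0.302 and 0.302. The skeletal muscle and antigen presentation calls ended without the arrays that stood apart (camera adjusted p = 0.0675 and 0.0622), and 127 probe sets passed. Omitting replicates 1, 2 and 3 in turn moved the count by over 1.5 times. Left gel gave 1, 12 and 0 (day 1) and 0, 0 and 2 (day 4). Left tPA gave 49, 54 and 1 (day 1) and 31, 0 and 3 (day 4).

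The injury response under gel differed between days in 141 probe sets (95 higher, 46 lower on day 4). Relative to sham, the class II genes RT1-Db1 and RT1-Ba and complement C3 were higher on day 4 than on day 1 (6.66, 4.17 and 6.36, with SE 0.98, 0.64 and 1.22). For RT1-Db1 sham arteries of day 1 lay above those of day 4, so its value is not the change of the injured artery alone. In the antigen presentation list 4 passed, with 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000776, and adjusted p = 0.177 with an estimated correlation). Macrophage markers were higher, C1qb (5.12) and Clec10a (2.91) passing, with 4 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000937, and adjusted p = 0.177 with an estimated correlation). Lymphocyte markers were higher, Cd3g (4.95) and Cd37 (2.78) passing, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000313, and adjusted p = 0.177 with an estimated correlation). Contractile genes were lower, Itga7 (-2.12) passing, with 0 higher and 5 lower adjusted over the list alone (camera adjusted p = 3.16e-05, and adjusted p = 0.177 with an estimated correlation). Skeletal muscle markers were lower, Myh7 (-6.59) passing, with 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 1.80e-08, and adjusted p = 0.177 with an estimated correlation). Ribosomal protein genes were lower, Rpl17 (-2.40) and Rpl30 (-2.76) passing, with 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000371, and adjusted p = 0.285 with an estimated correlation). Scn7a and Sncg were higher (9.64 and 7.75), a second probe set of Scn7a having -0.06. With the 4 tPA arrays that stood apart left out, 295 probe sets passed. When 1 array was left out the count moved by over 1.5 times, as omitting left gel day 1 replicate 2 gave 72.

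**Figure D3:**
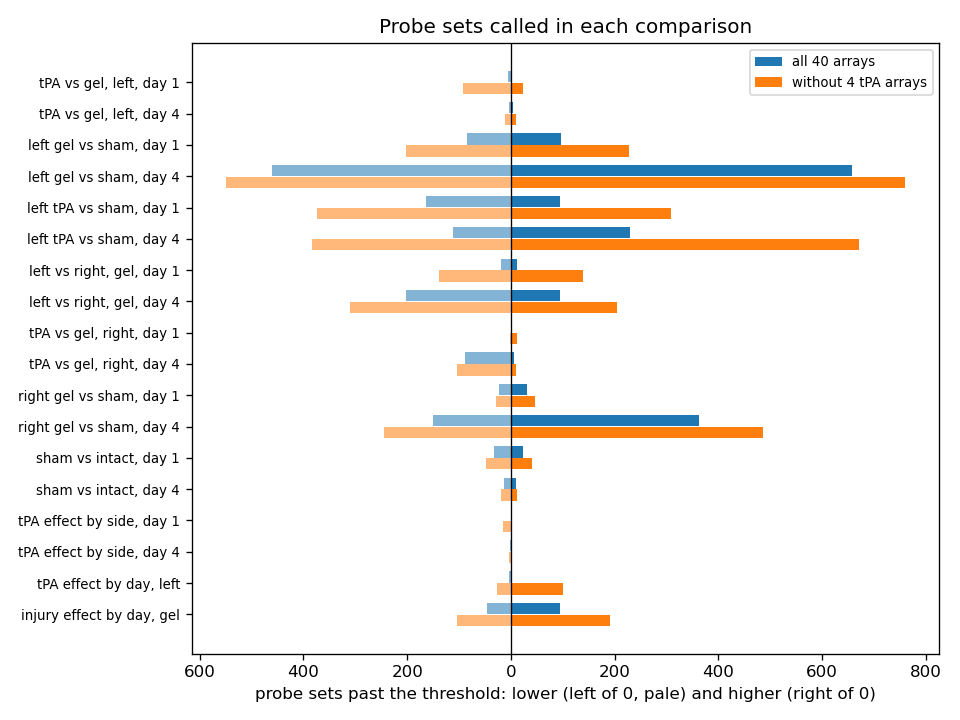
Number of probe sets past the threshold (horizontal axis, lower to the left of 0 and higher to the right) in each of the 18 comparisons (vertical axis), with all 40 arrays in blue and without the 4 tPA arrays that stood apart in orange. Left gel against sham on day 4 had 657 higher and 460 lower, and tPA against gel in the left artery had 7 in all on day 1 and 7 on day 4.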

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

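The tests of the 3 patterns weighed here were chosen only after the results were seen, while the tests of differences between effects and of values far from the rest of a group were planned. Of 235 sets of values in groups of 4 to 6 arrays, 20 held such a far value, where chance marks about 1 in 20 groups, or 11.75.

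The injury index of 4 tPA arrays stood apart from their group: it was 1.25 and 1.30 in 2 arrays labelled right and -0.66 and -0.18 in 2 labelled left. Poor RNA or hybridisation is argued against for left tPA day 4 replicate 1 and right tPA day 1 replicate 2, of which 0 lay outside the second lowest to the second highest value of the other 36 arrays in any of 3 quality measures. For the other 2 arrays, both outside, it cannot be told apart. Right tPA day 4 replicate 1 had GAPDH and actin 3'/5' ratios of 0.333 and 4.95 against 1.41 and 7.38 at the lower end (left tPA day 1 replicate 3, not one of the 4, had 0.243 and 2.80). Such low ratios are the opposite of a loss of 5' signal, so they set the array apart without showing degraded RNA. Left tPA day 1 replicate 2 had a GAPDH ratio of 11.44 against 9.92 at the upper end, the side of a loss of 5' signal. An exchange of labels in 2 pairs (right tPA day 4 replicate 1 with left tPA day 1 replicate 2, and left tPA day 4 replicate 1 with right tPA day 1 replicate 2) may explain them, as 4 of 4 were closest to the gel group of the supposed partner, but it cannot be told apart, since the pairs were read from the same values and only 1 of the 4 other right tPA arrays was closest to its own gel group (4 of 4 on the left). Uneven injury, with an index of at least 1.25 in the right pair, and uneven injury or an effect of tPA, with at most -0.18 in the left pair, cannot be told apart from it either, since the arrays were picked by this index.

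Cell cycle genes were lower in left tPA than in left gel arteries on day 1, with a mean difference of -1.41 over the list. The difference was -1.35 without the arrays that stood apart and -1.55 with each array shifted to one median, which argues against the array in doubt and against scaling as the whole cause, and it was -1.37 with the most alike left gel pair averaged. Uninjured muscle tissue in the left gel arrays is argued against. Right tPA day 1 replicate 3 and right gel day 4 replicate 1 had high muscle scores and cell cycle means of at most -0.21. Left gel arrays had 1.01 to 1.31. Injured muscle cannot be told apart, as left tPA day 1 replicate 3, which also scored high, belongs to the low group. The exchange of labels named above is argued against as the cause of the difference. The array it would bring into left tPA day 1, right tPA day 4 replicate 1, had -0.25. RNA quality cannot be told apart, since 2 of the 3 left tPA arrays lay below every left gel array of day 1 in both control 3'/5' ratios. For the tPA arrays that is the side opposite to a loss of 5' signal. Left gel arrays of day 4, with actin ratios of 7.38 to 8.09, had cell cycle means of 0.95 to 1.15. An effect of tPA on cell division stays open as a hypothesis, found and tested on the same data.

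Some bright probe sets read near 0 on single arrays: 55 of 956 bright ones did so, in 207 values. In 23 called changes, up or down, of 12 genes that have other probe sets, the others moved by a median over genes of -0.00279 of the change (quartiles -0.175 and 0.125). Loss or gain of the transcript is argued against for 9 genes, whose others moved by at most 0.0757 of the change in the same direction. It cannot be told apart from a failed reading for the 3 others: Cd74, whose other probe sets moved with it (0.581 and 1.08 of the change in 2 comparisons), Obp3 (0.222 and 0.407) and Igf1 (0.272). A failed reading of single probe sets is a candidate explanation for the 9, and splice forms that the probe sets read differently stay open. Where a whole group read near 0, either would have to be shared by its arrays, and why was not tested.

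In sham arteries of day 1 a value lay far from the other 3, by its gap over the range of the group. That ratio was 0.88 for the actin 3'/5' ratio (replicate 4, 16.3 against a median of 21 in the others), 0.922 for Myh7 (replicate 1, low), 0.861 for Ptgfr (replicate 4, high) and 0.89 for Dbp (replicate 2, low). It was 1, with all other arrays of the group at the floor, for Col1a2, Myl3, Cxcl2 and Enpp3 in sham day 1, for Rgs18 in sham day 4 and for Pde7a in intact arteries. In sham arteries of day 4 the ratio was 0.724 for the injury index, 0.679 for actin 3'/5' and 0.634 for C3 (all replicate 2, low, high and high). For the matrix protease list and Cfd (both replicate 3, low) it was 0.699 and 0.654, and for Scn7a (replicate 1, high), RT1-Db1 (replicate 5, low) and Ly86 (replicate 6, high) it was 0.704, 0.686 and 0.767. In intact arteries it was 0.64 for the cell cycle list (replicate 6, high) and 0.645 for Nr1d2 (replicate 5, low).

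Effects differed between groups in tests of the difference itself, given as log2 values. The tPA effect on the left minus that on the right was -1.91 for the cell cycle, 0.91 for the adipocyte and -2.43 for the skeletal muscle list on day 1. On day 4 it was -0.70 for matrix, -0.63 for cytokine, -0.68 for macrophage, 0.64 for adipocyte, 1.76 for nerve and -0.21 for ribosomal protein lists, with 3 probe sets past the threshold, Resp18 (3.83) and Rab4b (-3.84) among them. The left tPA effect of day 4 minus that of day 1 was 0.69 for contractile, 1.19 for cell cycle and 1.75 for skeletal muscle lists. It was -0.60 for cytokine, -1.002 for macrophage, -0.94 for lymphocyte, -1.18 for endothelial, -0.96 for adipocyte, -1.71 for nerve and -0.70 for antigen presentation lists. There 5 probe sets passed, with Mmp16 (2.35), Apod (-5.89), Rab4b (-3.35) and Selp (-2.86). All these comparisons hold arrays that stood apart, and of these list calls only cell cycle by side on day 1 held with an estimated correlation, in the fit with all arrays. Without the arrays that stood apart the right tPA effect on that list was 4.27e-05 in place of 0.50. The label exchange weighed above would bring an array with a nerve list mean of 1.88 into right tPA day 4 in place of 1 with -0.35, so the size of the nerve differences that use this group stays open to it. Right tPA day 4 replicates 2 and 3, which it leaves in place, had -0.50 and -0.49, against 1.70 to 2.41 in right gel. This argues against the exchange, though not against nerve tissue on the vessel, as the whole cause of that difference.

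The injury effect under gel on day 4 minus that on day 1, which also holds any difference between the sham groups of both days, passed in 141 probe sets. It was -0.78 for contractile, -2.67 for skeletal muscle, -0.42 for ribosomal protein, 1.47 for macrophage, 1.70 for lymphocyte and 1.01 for antigen presentation lists, none of which held with an estimated correlation. It was above 0 for Scn7a (9.64), Sncg (7.75), RT1-Db1 (6.66), C3 (6.36), C1qb (5.12), Clec10a (2.91), Cd3g (4.95), Cd37 (2.78), RT1-Ba (4.17) and RT1-DMb (3.38). It was below 0 for Col1a2 (-10.68), Apoe (-7.01), Myh7 (-6.59), Snrnp70 (-3.85), Itga7 (-2.12), Rpl17 (-2.40) and Rpl30 (-2.76), of which Col1a2, Apoe and Snrnp70 were read by probe sets that fell near 0 on some arrays.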

How the results depend on the processing

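The settings without the 4 tPA arrays that stood apart, without collapsing probe sets and with left gel day 1 replicates 1 and 3 averaged, and the list tests without right gel day 1 replicate 3, were chosen only after the results were seen, and all others were planned. Main counts were: left tPA against gel day 1 (7), left tPA against gel day 4 (7), left gel against sham day 1 (182), left gel against sham day 4 (1117), left tPA against sham day 1 (258), left tPA against sham day 4 (342), left against right gel day 1 (32), left against right gel day 4 (297), right tPA against gel day 1 (0), right tPA against gel day 4 (95), right gel against sham day 1 (54), right gel against sham day 4 (514), sham against intact day 1 (55), sham against intact day 4 (22), tPA by side day 1 (0), tPA by side day 4 (3), tPA by day (5) and injury by day (141). A count is given below where it moved by over 1.5 times, and the cause was not tested except where stated. All 18 counts stayed within that range with trend and robust moderation and without collapsing probe sets, which held 266 of 268 gene calls and 246 of 247 gene calls on the same side of the threshold. The 247 leave out the gene calls made through collapsing probe sets.

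Scaling and filtering each moved 3 to 8 of the 18 counts. Quantile normalization gave left tPA against gel day 1 (11), sham against intact day 4 (10) and tPA by day (25), holding 245 of 268 gene calls and 82 of 101 list calls. Median scaling gave left tPA against gel day 1 (41), left against right gel day 1 (65) and tPA by day (10), holding 262 of 268 gene calls. With the dimmer 50% of probe sets left out the counts were left tPA against gel day 1 (29), right tPA against gel day 4 (61) and tPA by day (3), and with no filter left tPA against gel day 4 (12), tPA by side day 1 (1), tPA by side day 4 (21) and tPA by day (1), the setting that tests more probe sets. They held 212 of 212 gene calls, counted over the calls whose probe sets the stricter filter keeps, and 234 of 268 gene calls. A floor at the 40th percentile gave left tPA against gel day 1 (41), left tPA against gel day 4 (16), left against right gel day 1 (69), left against right gel day 4 (457), right tPA against gel day 4 (163), tPA by side day 1 (3), tPA by side day 4 (37) and tPA by day (13), holding 262 of 268 gene calls.

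Array weights, the groups fitted and a block each moved 13 or 14 counts. Array weights gave left tPA against gel day 1 (128), left tPA against gel day 4 (339), left gel against sham day 1 (1430), left gel against sham day 4 (1831), left tPA against sham day 4 (1400), left against right gel day 1 (717), left against right gel day 4 (1002), right gel against sham day 4 (942), sham against intact day 1 (312), sham against intact day 4 (51), tPA by side day 1 (6), tPA by side day 4 (52), tPA by day (255) and injury by day (735), holding 263 of 268 gene calls. With only the groups compared, which leaves fewer arrays for the spread, the counts were left tPA against gel day 1 (0), left tPA against gel day 4 (0), left gel against sham day 1 (459), left tPA against sham day 1 (54), left tPA against sham day 4 (16), left against right gel day 1 (51), left against right gel day 4 (555), right tPA against gel day 4 (40), sham against intact day 1 (109), sham against intact day 4 (6), tPA by side day 4 (1), tPA by day (1) and injury by day (395), holding 179 of 268 gene calls. With the replicate number as a block, a pairing the labels do not give, they were left tPA against gel day 1 (0), left tPA against gel day 4 (0), left gel against sham day 4 (691), left tPA against sham day 1 (1), left tPA against sham day 4 (0), right tPA against gel day 4 (30), right gel against sham day 1 (12), right gel against sham day 4 (268), sham against intact day 4 (0), tPA by side day 1 (1), tPA by side day 4 (1), tPA by day (0) and injury by day (345), holding 142 of 268 gene calls and 95 of 101 list calls.

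Without the 4 tPA arrays that stood apart the counts were left tPA against gel day 1 (115), left tPA against gel day 4 (21), left gel against sham day 1 (430), left tPA against sham day 1 (682), left tPA against sham day 4 (1053), left against right gel day 1 (277), left against right gel day 4 (516), right tPA against gel day 1 (13), sham against intact day 1 (89), tPA by side day 1 (16), tPA by side day 4 (5), tPA by day (127) and injury by day (295), holding 265 of 268 gene calls and 84 of 101 list calls. That choice rests on the outcome and lowers the shared spread by construction. With left gel day 1 replicates 1 and 3 averaged, which leaves that group 1 array fewer, they were left tPA against gel day 1 (0), left gel against sham day 1 (94), left against right gel day 1 (2) and tPA by day (0), holding 35 of 58 gene calls. With the mean of a gene's probe sets 250 of 268 gene calls and 93 of 101 list calls held. Without right gel day 1 replicate 3, 13 of 15 list calls held in the comparisons with that group. With an estimated correlation 5 of 101 list calls held.

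Leaving out each array in turn gave these counts, from lowest to highest, day 1 before day 4. Left tPA against gel had 0 to 132 and 0 to 17. Left gel against sham had 90 to 115 and 723 to 1066. Left tPA against sham had 27 to 485 and 6 to 877. Left against right gel had 0 to 61 and 79 to 190. Right tPA against gel had 0 to 4 and 34 to 92. Right gel against sham had 16 to 71 and 175 to 542. Sham against intact had 36 to 53 and 0 to 24. The tPA effect by side had 0 to 9 and 2 to 12. By day, tPA had 0 to 54 and injury 72 to 150. Of the gene calls 1648 of 2258 held. A fit with 1 array fewer has less power by construction, and the cause of higher counts was not tested.

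Signs turned in left tPA against gel for genes that did not pass. Col1a1 on day 1 had 0.09 (-0.20 to 0.42 with single arrays left out) but -0.0413 with quantile normalization, -0.0551 with median scaling, -0.0744 with array weights, -0.20 without the 4 arrays, -0.14 without left gel replicate 2 and -0.20 without left tPA replicate 2. Timp1 on day 1 had 0.19 (-0.00798 to 0.51 with single arrays left out) but -0.00798 without left gel replicate 1. Plaur on day 1 had 0.10 (-0.23 to 0.44 with single arrays left out) but -0.0415 with median scaling and -0.23 without left tPA replicate 1. Plat on day 4 had -0.25 (-0.63 to 0.37 with single arrays left out) but 0.0364 with array weights, 0.37 without the 4 arrays and 0.37 without left tPA replicate 1. Col1a1 on day 4 had -0.17 (-0.30 to 0.0287 with single arrays left out) but 0.0287 without left tPA replicate 3. Acta2 on day 4 had -0.19 but 0.35 with the mean of its probe sets. Plau on day 4 had -0.58 (-1.17 to 0.11 with single arrays left out) but 0.11 without the 4 arrays and 0.11 without left tPA replicate 1. Plaur on day 4 had -0.57 but 0.17 with array weights. The cell cycle list in right tPA against gel on day 1 had a mean of 0.50, and 4.27e-05 with its call ended without the 4 arrays, with the opposite direction in the list test. The cause was not tested.

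Signal over background limits dim genes: below the floor a change is understated or lost, and a gene at the floor has a bound only.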

Other observations

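The genes in the first 2 paragraphs were chosen only after their values were seen, while the tests on other splits of the arrays were planned. Genes of the circadian clock, no list fixed in advance, were followed in left and right arteries of ballooned rats. Against sham of day 4, Dbp and Nr1d1 fell in left gel (-2.60 and -2.13, limma adjusted p = 0.000612 and 0.000162) and in right gel arteries (-2.21 and -1.36, adjusted p = 0.00721 and 0.0184). Bmal1 rose in both (1.34 and 1.77, adjusted p = 0.0272 and 0.00845). Nr1d2 (-1.50 and -1.59, adjusted p = 0.0552 and 0.0685) and Per2 (-0.74 and -0.89, adjusted p = 0.166 and 0.136) did not pass in left gel or right gel. In left tPA arteries of day 4 the differences of Dbp, Nr1d1 and Bmal1 (-0.61, -0.30 and 0.83) did not pass, nor did left tPA against gel for these probe sets (adjusted p of at least 0.0976), though another probe set of Dbp rose there (3.56). On day 1 Bmal1 fell against sham in left tPA and right gel arteries (-1.70 and -2.06, adjusted p = 0.0327 and 0.0219) and did not pass in left gel (-1.36, adjusted p = 0.116). Dbp averaged 11.73 ± 0.36 (SD, n = 6) in intact, 8.17 ± 0.15 (SD, n = 4) in sham day 1 and 11.01 ± 0.50 (SD, n = 6) in sham day 4 arteries on the log2 scale.

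Sqle, Insig1, Msmo1, Acat2 and Scd2, genes of sterol and fatty acid metabolism, had differences above 0 between ballooned animals and sham of day 4. Sqle rose in left gel, left tPA and right gel arteries (1.40, 1.62 and 2.24, limma adjusted p = 0.00102, 0.00326 and 1.34e-05). Insig1 rose in left tPA and right gel (1.39 and 1.59) and did not pass in left gel (0.96). Msmo1 rose in left gel and left tPA (0.95 and 0.89) and did not pass in right gel (0.68). Acat2 rose in left gel and right gel (1.15 and 2.16), with 1.14 in left tPA (adjusted p = 0.0553), and was lower in right tPA than right gel on day 4 (-1.76, adjusted p = 0.0186). Scd2 rose in left gel and right gel (0.97 and 1.27) and did not pass in left tPA (0.74), and another of its probe sets had the opposite sign in sham against intact on day 4. Sqle averaged 8.47 ± 0.19 (SD, n = 6) in sham day 4 and 9.70 ± 0.55 (SD, n = 6) in intact arteries.

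Other splits of the same arrays into groups of the same sizes were counted, with 100 drawn where there were more. Against sham, the share of splits with as many probe sets was 1 of 35 for left gel and left tPA on day 1. On day 4 it was 1 of 84 for left gel and right gel and 2 of 84 for left tPA. Sham against intact had 1 of 100 on each day. These shares lay below 0.05, with no adjustment over comparisons. They argue against chance for left gel and right gel against sham day 4 and sham against intact day 4. Left gel and sham arrays of day 1 were alike in pairs, which the splits ignore, so chance stays open there. So it does for left tPA against sham day 4, where another split called 435. Right gel against sham day 1 had 1 of 35, but same-numbered arrays deviated together there and the splits ignore it. For injury by day (1 of 100) the splits exchanged gel and sham labels within each day. This removes the injury effect itself, so that share cannot decide whether the effect differed between days. Real counts and the highest of the other splits, against sham day 1, were 182 and 36 (left gel) and 258 and 34 (left tPA). Right gel had 54 and 13 there. For sham day 4 they were 1117 and 52 (left gel), 342 and 435 (left tPA) and 514 and 22 (right gel). Sham against intact had 55 and 3 on day 1 and 22 and 4 on day 4. Injury by day had 141 and 13. For 3 arrays against 3 the 10 splits are too few for a share under 0.05, with real and highest other counts of left tPA against gel day 1 (7 against 36), left tPA against gel day 4 (7 against 1), left against right gel day 1 (32 against 128), left against right gel day 4 (297 against 1), right tPA against gel day 1 (0 against 2) and right tPA against gel day 4 (95 against 7). Of 10 splits, 4 and 1 had as many probe sets for left tPA against gel on days 1 and 4. There were 2 and 1 for left against right gel, and 10 (the real count being 0) and 1 for right tPA against gel. Chance cannot be excluded for tPA by side day 4 (13 of 100, real 3, highest other 95) and tPA by day (6 of 100, real 5, highest other 33). Other splits called several times the real count in left tPA against gel day 1, left against right gel day 1, tPA by side day 4 and tPA by day, and up to 220 probe sets in tPA by side day 1, where the real count was 0, which all 100 splits reach, so that the share there says nothing. This points to a structure of the arrays beside the groups compared, and what it is was not tested.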
